A study of Rattus norvegicus with 12 samples.

How the data were processed

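The arcuate nucleus of 12 rats was measured on 2-colour cDNA arrays, 1 array per rat. Per the labels, RNA was labelled with Cy3 for each electroacupuncture rat and with Cy5 for the pooled control RNA, the arrays were read with a laser scanner, and the images were quantified with ImaGene. The labels name ImaGene version 4.2 and the file headers version 5.1. Per the file headers, the deposited spot files hold spot and local background intensity for each of 12288 spots in 48 printed blocks, not yet normalized. The authors' value table gives a log2 value for 11257 of these features and leaves out 1031 spots, among them the first row of each block.

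The authors' log2 values were compared with the spot files. In every column all values between -1 and 1 equalled minus the log2 of a Cy3 over Cy5 ratio rounded to 3 decimals, to within the 4 decimals printed, so the table is on the scale of log2(Cy5/Cy3). Its column medians lay between -0.01 and 0.09. Which normalization and centring the authors used is not given in the sources used here. At spots above an intensity of 2000 in both channels, 11 columns correlated with log2(Cy3/Cy5) of their own files at r between -1.00 and -0.97, across features. The column of 100Hz_NR replicate 1 reached -0.23. The Cy3 file listed for that array is byte for byte that of 2Hz_HR replicate 1. By a rule set before the data were examined, the array was left out, with an analysis including it and an analysis of the authors' table with all 12 samples as alternatives.

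Groups were taken from the sample titles. The treatment text is worded alike for high responders and non-responders, and the class follows the titles and the responder label. The labels name the arcuate nucleus as the source of the control RNA, while its extraction text and the design text name another tissue by DH or dorsal horn. Whether the pool holds another tissue was to be tested on genes that mark it. Without gene names that test could not be run, so every ratio against the pool is given with this open. Comparisons between groups do not depend on it.

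Signal Mean was corrected for Background Median by normexp with an offset of 50, and each array was normalized by global loess with spots outside the value table at weight 0 (limma 3.58.1 in R 4.3.3). Ratios were taken as log2(Cy3/Cy5), the stimulated rat over the pool. Spots marked by hand as poor were set missing, and spots the software called empty were kept. A feature was tested if its Signal Mean exceeded the mean background by 2 background SDs in at least 1 channel on at least 50% of the arrays, which kept 9318 features, 82.8%. Saturated spots were kept. Signal over background was the only measure of depth. The number of arrays limits the precision, and p-values against the pool leave out the spread between control rats.

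All 4 groups were fitted together with lmFit and eBayes of limma, so they share 1 estimate of the spread. Tests are two-sided. Each group and the mean of the 4 groups were tested against 0, since the pool is 1 control sample, and 7 contrasts between groups were tested, 12 comparisons in all. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over the features of that comparison. No array had the opposite dye orientation, so dye bias of single features stays in the comparisons with the pool.

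The rule for named genes, the largest called changes with a gene symbol whose replicates all lay on 1 side, could not be met as written, because 0 feature names hold a symbol or accession. The fixed gene lists, their camera tests and the always-named genes were not run for the same reason. Instead the rule was applied without the symbol, and the text prints the 2 higher and the 2 lower features that stood most often among the first 2 of the 5 comparisons with the pool. This selection was made after the values were seen.

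The date of quantification was read from the file headers. Its day of the month is called quantification day here. Its year is called clock setting, on the untested assumption that the years differ by the setting of the computer's clock. Arrays of 1 quantification day can thus carry different years, and each day holds arrays of both. The second day holds 100Hz_HR replicate 3 and 100Hz_NR, and the second clock setting holds 2Hz_HR replicates 2 and 3 and 100Hz_NR. Both are confounded with the groups, for some comparisons wholly: 2Hz_NR and 100Hz_NR share neither day nor setting, and 100Hz_HR and 100Hz_NR share no setting. Fits with each as a block and within each were added after seeing the data. Alternatives fixed before the data were examined changed background correction, spot summary, normalization, the filter, marked spots, the arrays used, the replicate number as a block, array weights, the groups in the fit, a fold minimum of 1.5 and each array left out in turn.

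The test was run on simulated data with the 9318 features, the real design and 200 features changed 1.2-fold to 3-fold. For 2Hz_HR against the pool it called 70.0% of features changed 1.5-fold and 98.0% of those changed 2-fold, and for all groups against the pool 90.0% and 96.0%. Unchanged features were drawn without any difference from the pool, so dye bias and the spread between control rats are left out. The shares against the pool hold only in their absence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.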

Results

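RNA of the arcuate nucleus, a cell group at the base of the hypothalamus, was profiled in Sprague-Dawley rats after electroacupuncture, the electrical stimulation of needles placed at acupuncture points. Rats were stimulated for 30 min at 2 Hz or 100 Hz, tested for pain sensitivity, and returned to their cages for 1 h before tissue was taken. By their analgesic response they had been divided into high responders (HR) and non-responders (NR), which gives 4 groups of 3 rats, named here 2Hz_HR, 2Hz_NR, 100Hz_HR and 100Hz_NR. Each rat's RNA, labelled with Cy3, was hybridised on its own 2-colour array against a Cy5-labelled mixture from 3 control rats that were not stimulated. The same mixture stood on every array and counts as 1 control sample.

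Of the 12 arrays, 11 entered the comparisons. The Cy3 file listed for 100Hz_NR replicate 1 was identical to that of 2Hz_HR replicate 1, so that array was left out and 100Hz_NR had n = 2. The arrays used had median Cy3 intensities from 425 to 598 and median Cy5 intensities from 423 to 592 over the 11257 features of the authors' value table. Between 80.3% and 88.9% of these features lay above background in Cy3, and between 71.8% and 79.8% in Cy5, and 9318 features were tested. Precision is limited by the number of arrays. The files name features only by their place on the slide (for example Sr08Sc02R12C12, the row and column within a printed block). They do not pair features with genes, so no gene, pathway or cell type can be named. Only 2 features higher and 2 lower than the pool are given.

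Log2 ratios below are of the electroacupuncture rat over the control pool, Cy3 over Cy5. This direction is opposite to that of the authors' value table, which holds the log2 of Cy5 over Cy3.

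The first question was which transcripts differed from the unstimulated pool over all 4 groups. Feature Sr08Sc02R12C12 was 2.66-fold above the pool (log2 ratio 1.41, SE 0.10, adjusted p = 9.4e-05 by limma with Benjamini-Hochberg adjustment). It was higher on 11 of 11 arrays, with single arrays between 0.63 and 1.97 on the log2 scale. Feature Sr02Sc02R03C06 was 3.75-fold above the pool (log2 ratio 1.91, SE 0.09, limma and Benjamini-Hochberg adjusted p = 2.8e-05). It was higher on all 10 arrays on which it had a value. Feature Sr02Sc02R02C03, bright in both channels, had a log2 ratio of -0.58 (SE 0.04, limma and Benjamini-Hochberg adjusted p = 9.0e-05). It was lower on 11 of 11 arrays. Feature Sr02Sc03R14C13 passed the threshold as lower (limma and Benjamini-Hochberg adjusted p = 0.00136) and was lower on 10 of 11 arrays, but its Cy3 signal lay above background on 2 of the 11, so the size of its change was not measured. Over the alternatives the first 2 lost the call in 0 of 29, Sr02Sc02R02C03 in 1 of 29 and Sr02Sc03R14C13 in 0 of 28. The filter asking for both channels above background on every array removes Sr02Sc03R14C13, so that alternative is not among its 28. No alternative changed the pool or the dye orientation, so none could undo a call that came from either.

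In total 2887 of 9311 features passed the threshold over all 4 groups, 1559 higher and 1328 lower than the pool. Most of these differences were small: the median called change was 1.13-fold, and 33 higher and 5 lower features reached 1.5-fold. The test sets the rats against a single pool in a single dye orientation, so it leaves out the spread between control rats and does not remove dye bias of single features, and the labels name both the arcuate nucleus and the dorsal horn for the pool, which could not be settled without gene names. The share of called features that were higher, 54.0%, was 36.8% with median centring in place of loess and 40.5% in the authors' value table.

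Counts for the single groups were smaller. The limits of the single pool and the single dye orientation hold for each group as well. In 2Hz_HR, 160 features were higher and 75 lower than the pool. Feature Sr08Sc02R12C12 was 2.34-fold above the pool (log2 ratio 1.23 ± 0.52, SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.0204), and Sr02Sc02R02C03 had a log2 ratio of -0.64 ± 0.12 (SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.00908). Feature Sr02Sc02R03C06 had a log2 ratio of 1.68 ± 0.54 (SD, n = 2 arrays with a value, limma and Benjamini-Hochberg adjusted p = 0.0120). Feature Sr02Sc03R14C13 did not pass in this group (limma and Benjamini-Hochberg adjusted p = 0.765), and no ratio is given, since neither channel lay above background on any of the 3 arrays. Over the alternatives, Sr08Sc02R12C12 lost its call in 8 of 33, Sr02Sc02R02C03 in 6 of 33 and Sr02Sc02R03C06 in 5 of 32. The count of 235 fell to 4 without 2Hz_HR replicate 1, to 4 without 2Hz_HR replicate 3 and to 55 without 2Hz_HR replicate 2. It was 0 when the group was fitted alone, 3081 (1168 higher, 1913 lower) with median centring and 415 (376 higher, 39 lower) with quantification day as a block. With the clock setting, the year in the date of quantification, as a block it was 129, and within the second clock setting it was 0. Only this group spans both settings, so the clock block rests on its replicate 1 against its replicates 2 and 3 in every comparison, and within the first setting 2Hz_HR is 1 array. Likewise only 100Hz_HR spans both days, so the day block rests on 100Hz_HR replicate 3 against its own group in every comparison.

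In 2Hz_NR, 171 features were higher and 114 lower than the pool. Feature Sr02Sc02R03C06 was 4.36-fold above the pool (log2 ratio 2.12 ± 0.30, SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.00207) and Sr08Sc02R12C12 was 2.77-fold above it (1.47 ± 0.44, SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.0103). Feature Sr02Sc02R02C03 had a log2 ratio of -0.69 ± 0.00 (SD 0.0032, n = 3, limma and Benjamini-Hochberg adjusted p = 0.00732). Feature Sr02Sc03R14C13 passed as lower (limma and Benjamini-Hochberg adjusted p = 0.0454), but no size is given, since Cy3 lay above background on 1 of 3 arrays and the log2 ratio ranged from -2.81 to -0.49 over the alternatives. It lost its call in 22 of 31 of them, Sr08Sc02R12C12 in 7 of 32, Sr02Sc02R02C03 in 6 of 32 and Sr02Sc02R03C06 in 1 of 32. The count of 285 fell to 7, 20 and 6 without 2Hz_NR replicates 1, 2 and 3, and was 0 with the group fitted alone. It was 2606 (1091 higher, 1515 lower) with median centring, 245 (231 higher, 14 lower) with quantification day as a block, 7 with the clock setting as a block and 6 within the first clock setting.

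In 100Hz_HR, 69 features were higher and 68 lower than the pool. Feature Sr02Sc02R03C06 was 3.58-fold above the pool (log2 ratio 1.84 ± 0.31, SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.00804) and Sr08Sc02R12C12 was 2.81-fold above it (1.49 ± 0.15, SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.0172). Feature Sr02Sc02R02C03 had a log2 ratio of -0.58 ± 0.21 (SD, n = 3, limma and Benjamini-Hochberg adjusted p = 0.0206). Feature Sr02Sc03R14C13 passed as lower (limma and Benjamini-Hochberg adjusted p = 0.0443), again without a size, with Cy3 above background on 1 of 3 arrays and a log2 ratio from -2.67 to -0.75 over the alternatives. It lost its call in 22 of 32 of them, Sr02Sc02R02C03 in 10 of 33, Sr08Sc02R12C12 in 9 of 33 and Sr02Sc02R03C06 in 6 of 33. The count of 137 fell under every omission of 1 array, to 2 without 100Hz_HR replicate 3 and 48 at most. It was 0 with the group fitted alone, 3761 (1371 higher, 2390 lower) with median centring and 903 (663 higher, 240 lower) with quantification day as a block. It was 4 with the clock setting as a block, 3 within the first day and 1 within the first clock setting. Within the second day this group is 1 array, so no count is given.

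In 100Hz_NR, with 2 arrays, 6 features were higher and 0 lower than the pool, among 1194 at an unadjusted p under 0.05. Feature Sr02Sc02R03C06 was 3.97-fold above the pool (log2 ratio 1.99 ± 0.03, SD, n = 2, limma and Benjamini-Hochberg adjusted p = 0.0141). Feature Sr08Sc02R12C12 had a log2 ratio of 1.45 ± 0.11 (SD, n = 2, limma and Benjamini-Hochberg adjusted p = 0.0920), which did not pass. Nor did Sr02Sc02R02C03, with a log2 ratio of -0.42 ± 0.08 (SD, n = 2, limma and Benjamini-Hochberg adjusted p = 0.151), or Sr02Sc03R14C13 (limma and Benjamini-Hochberg adjusted p = 0.198), whose Cy3 signal lay above background on 0 of 2 arrays. Over the alternatives, Sr02Sc02R03C06 lost its call in 8 of 32, Sr08Sc02R12C12 gained one in 3 of 32 and Sr02Sc02R02C03 in 2 of 32. With quantification day as a block 212 features passed, where the direction turned over to 25 higher and 187 lower. All 100Hz_NR arrays are of the second day, so that shift rests on 100Hz_HR replicate 3 against its own group. The count was 0 with the group fitted alone, 2 with the clock setting as a block, and 0 within the second day and within the second clock setting. It was 99 (44 higher, 55 lower) in the authors' table with all 12 samples and 1852 (849 higher, 1003 lower) with median centring. It was 29 without 100Hz_NR replicate 2 and 13 without 100Hz_NR replicate 3, where the lone array left was assumed to vary like the other groups.

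**Figure D1:**
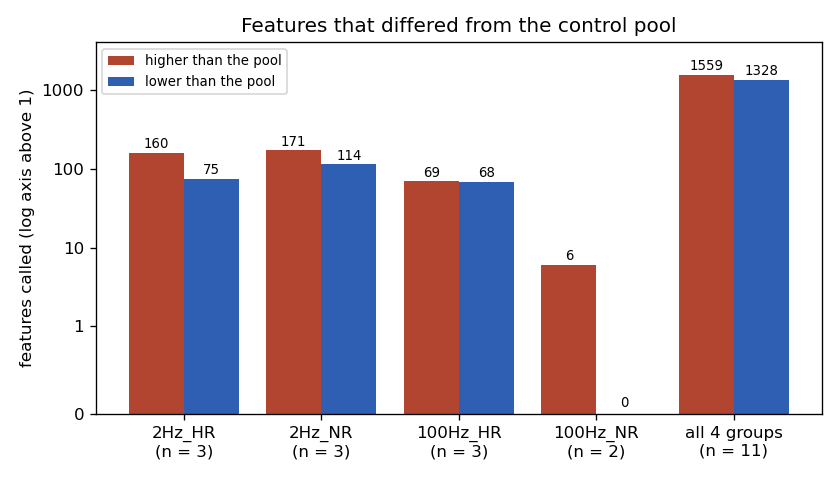
Number of features (vertical axis, logarithmic above 1) called higher (red) or lower (blue) than the control pool by limma with Benjamini-Hochberg adjustment, for each group and for the mean of the 4 groups, with n the number of arrays. The mean of the 4 groups gave 1559 higher and 1328 lower features, and 100Hz_NR gave 6 and 0.

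A call in 1 group and not in another does not show that the groups differ, so the differences were tested directly. In these comparisons the RNA of the pool and the dye orientation are common to both sides and cancel. Variation of the Cy5 signal from array to array does not cancel and enters these ratios. No ID is given for them, since no feature passed.

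High responders and non-responders were compared to ask which transcripts go with the analgesic response. At 2 Hz, limma with Benjamini-Hochberg adjustment called 0 of 9314 features (lowest adjusted p = 0.766). At an unadjusted p under 0.05 there were 412, where evenly spread p-values give about 466. The 412 became 965 with array weights, 789 with the replicate block and 184 without 2Hz_HR replicate 3, so it moved to both sides of 466. Of the 10 splits of these rats into 3 and 3, the real one included, 3 gave at least 412. The groups did not overlap at 17.1% of features, where chance gives 10% for 3 rats against 3. The 95% confidence interval of a log2 difference had a median half-width of 0.26, or 1.19-fold. The 95th percentile of the half-width over features was 0.76, or 1.70-fold. These intervals are not adjusted for the number of features. The count was 0 with quantification day as a block and within the first day, 3 with the clock setting as a block and 1 within the first clock setting, where a single 2Hz_HR array is assumed to vary like the other groups.

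At 100 Hz, limma with Benjamini-Hochberg adjustment called 0 of 9312 features between HR and NR (lowest adjusted p = 1.00), with 176 at an unadjusted p under 0.05. The groups did not overlap at 11.5% of features, where chance gives 20% for 3 rats against 2. The median half-width of the 95% interval was 0.29 on the log2 scale, or 1.22-fold, and its 95th percentile over features was 0.85, or 1.80-fold. With quantification day as a block 360 features passed, 357 of them higher in HR. All 100Hz_NR arrays and, in 100Hz_HR, only replicate 3 were quantified on the second day, so in that fit the day effect rests on 100Hz_HR replicate 3 against the other arrays of its group. Within the second day 100Hz_HR has 1 array, so that fit cannot weigh the 360. The 2 groups share no clock setting, so the clock effect comes from 2Hz_HR. With the clock setting as a block the count was 1. It was 14 without 100Hz_NR replicate 2, with 0 higher in HR, and 7 without 100Hz_NR replicate 3, with 2 higher, so mostly in the opposite direction.

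Over both frequencies, limma with Benjamini-Hochberg adjustment called 0 of 9311 features between HR and NR (lowest adjusted p = 0.970), with 227 at an unadjusted p under 0.05. The half-width had a median of 0.19 on the log2 scale, or 1.14-fold, and a 95th percentile over features of 0.57, or 1.49-fold. The 227 became 475 with the replicate block and 146 without 2Hz_HR replicate 3. The classes did not overlap at 0.25% of features, where chance gives 0.43% for 6 rats against 5. The count was 254 with quantification day as a block, which rests on the same array, all higher in HR, and 0 with the clock setting as a block. It was 10 and 2 without 100Hz_NR replicates 2 and 3, all lower in HR.

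The frequencies were compared in the same way. Between 2Hz_HR and 100Hz_HR, limma with Benjamini-Hochberg adjustment called 0 of 9318 features (lowest adjusted p = 0.821), with 470 at an unadjusted p under 0.05. The groups did not overlap at 10.9% of features, close to the 10% of chance. The count was 4 with the clock setting as a block, 1 within the first clock setting, again with a single 2Hz_HR array, and 0 with quantification day as a block and within the first day. Between 2Hz_NR and 100Hz_NR, limma with Benjamini-Hochberg adjustment called 0 of 9311 features (lowest adjusted p = 1.00), with 164 at an unadjusted p under 0.05. The 164 became 283 with the replicate block and 105 without 2Hz_NR replicate 1. These groups did not overlap at 14.4% of features, where chance gives 20%. 2Hz_NR and 100Hz_NR share neither quantification day nor clock setting, so each block effect comes from arrays of other groups. The number called was 220 with quantification day as a block, all higher at 2 Hz, and 1 with the clock setting as a block. It was 17 and 4 without 100Hz_NR replicates 2 and 3, all lower at 2 Hz.

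Over both responder classes, limma with Benjamini-Hochberg adjustment called 0 of 9311 features between 2 Hz and 100 Hz (lowest adjusted p = 0.998), with 308 at an unadjusted p under 0.05. The frequencies did not overlap at 0.41% of features, where chance gives 0.43%. The number called was 61 with quantification day as a block, all higher at 2 Hz, and 0 with the clock setting as a block. It was 10 and 2 without 100Hz_NR replicates 2 and 3, all lower at 2 Hz. The interaction asks whether the difference between HR and NR itself differed between the frequencies. It gave 0 of 9311 features by limma with Benjamini-Hochberg adjustment (lowest adjusted p = 0.933), with 209 at an unadjusted p under 0.05. The half-width had a median of 0.38 on the log2 scale, or 1.30-fold, and a 95th percentile over features of 1.14, or 2.21-fold. The count of the interaction was 195 with quantification day as a block (1 above 0, 194 below), 2 with the clock setting as a block, and 7 and 4 without 100Hz_NR replicates 2 and 3, all above 0.

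In simulated data with the residual spread of each feature, 70.0% of features changed 1.5-fold and 84.0% of those changed 2-fold were called between 2Hz_HR and 2Hz_NR. Between 100Hz_HR and 100Hz_NR the shares were 36.0% and 70.0%. For a 1.2-fold change they were 2.00% at 2 Hz and 0 at 100 Hz. The simulation draws features independently and so leaves out any component common to many features of an array.

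The arrays did not resemble each other more within groups than between them. Across 9202 features with a value on every array, the mean Pearson correlation was 0.250 within groups and 0.272 between groups (one-sided permutation p = 0.537, 100000 permutations of the group labels). The highest correlation, 0.836, joined 2Hz_NR replicate 1 and 100Hz_HR replicate 2, which share neither frequency nor responder class. The lowest was -0.31 over these features and -0.26 over all features. The dyes are stated on the labels, so the direction was kept. These correlations are across features, which are not independent replicates, and were examined after the data had been seen.

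**Figure D2:**
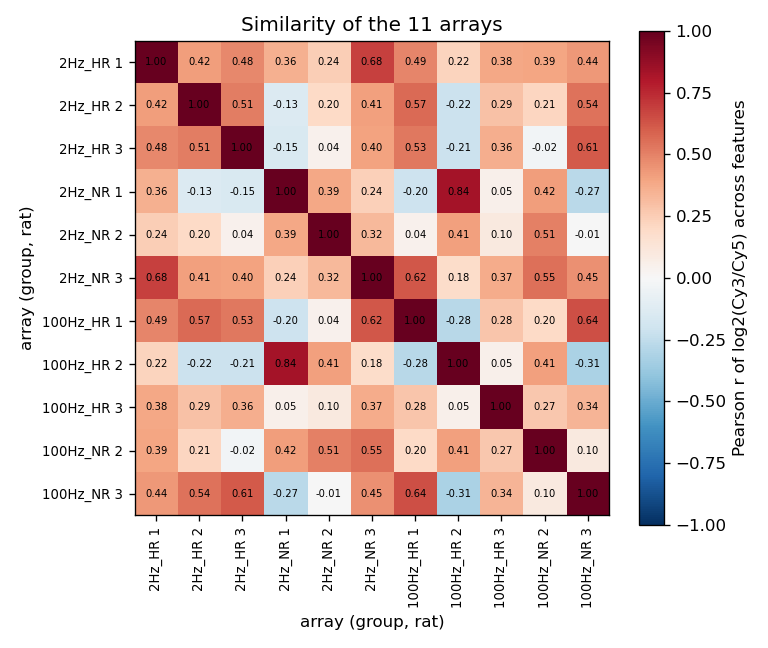
Pearson correlation of log2(Cy3/Cy5) across features between each pair of the 11 arrays, from -1 (blue) to 1 (red), with rats ordered by group on both axes. The pair 2Hz_NR 1 and 100Hz_HR 2 reaches 0.836, and the groups form no blocks of their own.

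A set of 226 features, found after the data had been seen, moved together over the arrays. Its median log2 ratio was 1.42 in 2Hz_NR replicate 1 and 1.42 in 100Hz_HR replicate 2, and 0.12 or lower in the other arrays. The groups did not differ in it beyond the spread between rats (permutation p = 0.634, one-sided, 100000 permutations).

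**Figure D3:**
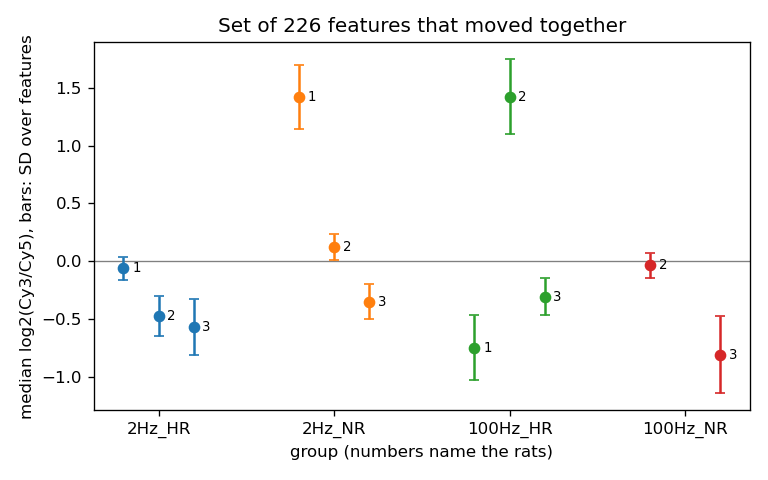
Median log2(Cy3/Cy5) of 226 features that moved together (vertical axis) for each rat, by group (horizontal axis, numbers name the rats), with bars for the SD over features. 2Hz_NR 1 and 100Hz_HR 2 reach 1.42, and the others lie between -0.81 and 0.12.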

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

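All tests in this part except the normalization test and the splits over all arrays were chosen after the result was seen.

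Spots outside the authors' value table were not used in the comparisons. In the first row of the 48 printed blocks, 16 positions hold 1 spot per block each, and what is printed there is not known. The position in column 7 had a mean log2(Cy3/Cy5) of 0.60 ± 0.56 (SD over 11 arrays), was above 0 on 11 of 11 arrays, and reached 3.78-fold on 2Hz_HR replicate 3. Columns 10 and 15 had means of 0.26 and 0.14 and were above 0 on 11 of 11 arrays. Each of the 3 gave an exact two-sided sign-flip p = 0.00098 (Benjamini-Hochberg adjusted p = 0.0026 over 16 positions), the smallest that 11 arrays can give. Columns 4, 9 and 16 gave the same p in the other direction, with means of -0.07, -0.06 and -0.18 and a ratio below 0 on 11 of 11 arrays. Columns 3, 6 and 13 also passed (exact two-sided sign-flip test, Benjamini-Hochberg adjusted p = 0.0039, 0.0039 and 0.0052). Their means were -0.12, -0.13 and -0.27, each with a ratio above 0 on 1 of 11 arrays. At least 99.8% of the spots in these columns lay above background in either channel, so these ratios are not of dim spots. In Cy5, 5.30% of the spots in column 10 and 21.2% of those in column 15 lay above background, and in columns 4 and 9 it was 12.5% and 6.63% in Cy3 and 7.58% and 2.08% in Cy5, so the ratios of these 4 are of dim spots.

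The excess over the control pool, 2887 features with a median change of 1.13-fold, may in part be dye bias that differs between features. Of the 16 positions, 6 kept 1 sign on all 11 arrays, among them the 4 dim ones. This count had been seen when its threshold was set, and 0 arrays have the opposite dye orientation, so dye bias and unequal RNA cannot be told apart here. The make-up of the single control pool stays open as well and was not tested, and so does the biological difference between stimulated and control rats.

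A set of 226 features moved together over the arrays (SD over arrays above 0.5, clustered at a correlation of 0.95), with a median log2 ratio of 1.42 in both 2Hz_NR replicate 1 and 100Hz_HR replicate 2 and -0.81 in 100Hz_NR replicate 3, and the Cy3 channel carried the movement, with a range of 2.28 against 0.27 in Cy5. Frequency or responder class alone does not account for it, since rats of 1 group lay up to 2.17 apart (permutation p of the 4 groups 0.634, one-sided). With so few rats per group, a smaller contribution of either is not excluded. Background correction and loess are argued against by a range of 1.94 or more without the one or the other. A regional defect of the slides or of the printing stays open: the set lay in 39 of 48 blocks, short of the 40 set for excluding it, with 91.2% of its features in block columns 3 and 4 of the 4 across, against 41.2% of tested features, and 93.4% in rows 2 to 5 and 9, against 39.4%. A difference between the RNA samples, such as dissection or the state of single rats, also stays open and was not tested.

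Other splits of the rats were compared by the number of features at an unadjusted p under 0.05. For 2Hz_HR against 2Hz_NR, 3 of the 10 splits gave at least the real 412, and the highest other gave 653. For 2Hz_HR against 100Hz_HR, 5 of the 10 gave at least 470, and the highest other gave 582. The 10 splits are too few for a share under 0.05. For high responders against non-responders, 73 of 100 splits within frequency gave at least 227, and for 2 Hz against 100 Hz, 49 of 100 within responder class gave at least 308, so chance cannot be excluded for either. The other splits had medians of 306 and 289, and 12 and 4 of the 100 splits gave over 3 times the real count. The highest gave 1484 and 1358, a hint of a structure of the samples that was not tested further. Both put 2Hz_NR replicate 1 and 100Hz_HR replicate 2 on the same side.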

How the results depend on the processing

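The alternatives with quantification day, clock setting or the set of 226 features that moved together were chosen after seeing the data; all others were planned. Counts are of features called by limma with Benjamini-Hochberg adjustment, and the cause of a shift was not tested unless stated. The count over all groups against the pool stayed within 1.5 times of 2887 except for 5926 with median centring, 1904 with 100Hz_NR replicate 1 included and 38 at a fold of at least 1.5, and between-group counts stayed at 0 except where given. The gene list and control pool alternatives were not run, since features have no gene names. Signal over background limits the dim features.

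For 2Hz_HR, 2Hz_NR, 100Hz_HR and 100Hz_NR against the pool (235, 285, 137 and 6), median centring gave 3081, 2606, 3761 and 1852, with 37.9%, 41.9%, 36.5% and 45.8% higher in place of 68.1%, 60.0%, 50.4% and 100.0%. Without background correction 2Hz_HR gave 30 (15 higher), 2Hz_NR 31 and 100Hz_NR 2, while 100Hz_HR had 34.6% higher. Signal Median gave 72 for 100Hz_HR, scaling between arrays 25 (76.0% higher), and print-tip loess 128 for 2Hz_HR and 90 for 2Hz_NR (71.1% higher). With no filter 2Hz_NR gave 165 and 100Hz_HR 37. With both channels above background everywhere 2Hz_HR gave 78 and 2Hz_NR 74. With all marked spots missing 2Hz_HR gave 128, 2Hz_NR 158, and 100Hz_HR against 100Hz_NR and against 2Hz_HR 1 each. With 100Hz_NR replicate 1 included the groups gave 16, 17, 4 and 11. The authors' table gave 76, 103 and 99 for 2Hz_HR, 2Hz_NR and 100Hz_NR (44.4% higher), and 40.5% higher against 54.0% over all groups. arrayWeights gave 1028, 1623 and 59 for 2Hz_HR, 2Hz_NR and 100Hz_HR. Each group fitted alone gave 0, with fewer arrays for the spread, and a fold of at least 1.5 gave 20, 40 and 23 for 2Hz_HR, 2Hz_NR and 100Hz_HR.

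With the replicate block, 2Hz_HR gave 364 and 100Hz_NR 2, and no between-group count moved. The labels do not say that the numbers pair rats: same-numbered rats of different groups correlated from -0.60 to 0.55 in their deviations, over 0.1 in 10 of 15 pairs, with a mean of 0.14 against -0.07 for different numbers, and 6 of 11 arrays correlated best with their own number. Not every pair passed 0.1, so the numbers were treated as names, but a batch behind them is not ruled out.

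With quantification day as a block 2Hz_HR, 100Hz_HR and 100Hz_NR gave 415, 903 and 212 against the pool, with 90.6%, 73.4% and 11.8% higher, and 2Hz_NR 245 with 94.3% higher. The direction of 100Hz_NR thus turned over. In the same fit 100Hz_HR against 100Hz_NR gave 360 (357 higher), 2Hz_NR against 100Hz_NR 220, HR against NR 254 and 2 Hz against 100 Hz 61 (all higher), and the interaction 195 (194 below 0). By construction that effect rests on 100Hz_HR replicate 3. With the clock setting as a block, which by construction rests on 2Hz_HR replicate 1 against replicates 2 and 3, the groups gave 129, 7, 4 and 2, and 2Hz_HR against 2Hz_NR 3, 2Hz_HR against 100Hz_HR 4, the interaction 2, and 100Hz_HR and 2Hz_NR against 100Hz_NR 1 each. Within the first day 100Hz_HR gave 3, and within the second 100Hz_NR gave 0. Within the first clock setting, with 1 array of 2Hz_HR, 2Hz_HR, 2Hz_NR and 100Hz_HR gave 2, 6 and 1, and 2Hz_HR against 2Hz_NR and against 100Hz_HR 1 each, and within the second 2Hz_HR and 100Hz_NR gave 0. The moving set as a covariate gave 126, 124 and 82 for 2Hz_HR, 2Hz_NR and 100Hz_HR, and without its 2 highest arrays the groups gave 36, 10, 0 and 2.

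Leaving out 1 array at a time gave 4 to 387 for 2Hz_HR, 6 to 477 for 2Hz_NR, 2 to 48 for 100Hz_HR, 5 to 29 for 100Hz_NR and 2070 to 2861 over all groups. Between groups it gave 0 for 2Hz_HR against 2Hz_NR and against 100Hz_HR, 0 to 14 for 100Hz_HR against 100Hz_NR, 0 to 17 for 2Hz_NR against 100Hz_NR, 0 to 10 for HR against NR and for 2 Hz against 100 Hz, and 0 to 7 for the interaction. Without 100Hz_NR replicate 2 or 3 the features called between groups went the other way from most of those under the day block, apart from 2 of the 7 of 100Hz_HR against 100Hz_NR. Of 981 alternative values of single features, 845 kept direction and side of the threshold, 133 lost and 2 gained the call, and 1 changed sign. The last was a feature lower in 100Hz_HR (-0.70), at 0.075 without background correction. The values include features of the comparisons between groups, which were not called and so had no call to lose. The 133 losses thus all fell on features called against the pool, and the 845 does not measure how stable those calls were.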

Other observations

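The groupings in this part were found after the data had been seen, and no explanation was tested for them. A set of 18 features was 4.24-fold above the pool in 100Hz_HR replicate 3 and between 0.97-fold and 1.10-fold on the other 10 arrays. All 18 lay in blocks Sr02 to Sr05 down the slide and Sc01 to Sc03 across it, so a regional defect of that 1 slide stays open. A set of 5 features took levels near the pool or near 2-fold above it: it lay between 0.97-fold and 1.10-fold in 2Hz_HR replicates 2 and 3, 2Hz_NR replicate 2, 100Hz_HR replicate 1 and 100Hz_NR replicate 3, and between 1.89-fold and 2.25-fold in the other 6 arrays, with both levels in each of the 4 groups. Cy5, the same pool on every array, carried part of this. Its log2 deviation from the mean over arrays was -0.41 to -0.004 at the higher level and 0.12 to 0.34 at the lower. In Cy3 the deviations were 0.06 to 0.55 and -0.44 to -0.18, so the levels do not reflect the rats alone. A set of 9 features had a median log2 ratio of -0.86 in 2Hz_HR replicate 2, -0.06 and -0.12 in 100Hz_NR replicates 2 and 3, and between 0.44 and 1.02 on the other 8 arrays. All but Sr12Sc03R10C14 lay in row R07 of their blocks and in block columns Sc01 and Sc02, so an effect of the printing stays open. Cy5, the common pool, also moved, with log2 deviations from -0.33 to 0.30, against -0.80 to 0.41 in Cy3. The spread in each channel was compared over the 9202 tested features with a value on every array, after quantile normalization between arrays. The SD between arrays was larger in Cy3, which carries the single rats, than in Cy5, which carries the same pool, in 66.6% of these features. The medians were 0.309 and 0.269 on the log2 scale.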
